A study of Mus musculus with 8 samples.

How the data were processed

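Gene expression was measured in haematopoietic stem cells (HSCs) sorted from the marrow of untreated C57Bl/6 mice. Per the labels' protocols, marrow was enriched for Kit-positive cells and sorted by flow cytometry. The gate took lineage-negative, Sca-1-positive, Kit-positive cells with high CD9 and CD150 and without CD48. The KO group came from mice with both Bmpr2 alleles floxed around exons 4 and 5 and with the Vav-Cre transgene, which is active in blood cells. The WT group came from littermates without Vav-Cre. Per the labels' protocols, each of the 4 KO and 4 WT samples pooled bones of 3 mice, while the series' design text speaks of 4 mice per group. The pools are therefore treated here as the replicates, n = 4 per group. Which litter, day or hybridisation batch each pool came from is not given in the sources used here.

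Per the labels' protocols, RNA was isolated with a column kit, amplified from very small amounts by single primer isothermal amplification (SPIA), labelled with biotin and hybridised to Affymetrix arrays, 1 per pool. Per the submitters' processing notes, intensities were processed with RMA in Affymetrix Expression Console 1.3. RMA subtracts background, makes the distributions of probe intensities alike on all arrays and then sums the probes of a probe set on the log2 scale. It can therefore hide a change shared by most genes, and it gives dim probe sets values close to the background, so their differences are compressed. The deposited values are log2 levels between 1.47 and 13.3, for 28853 probe sets on 8 arrays. They stand in a table of values and again in an annotated table, and the tables differ by at most 1.8e-15. The annotated table also holds the authors' own comparison of KO with WT. Its deposited log2 ratio equals the difference of the group means, its deposited fold change carries a minus sign where KO was lower, and its deposited p-value, not adjusted, equals that of a 2-sided test of the means with equal variances. The genome build and annotation release behind the probe sets are not given in the sources used here, so no coordinates are printed.

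Gene symbols were taken from the authors' annotated table. Of the probe sets, 23586 had exactly 1 symbol, 5188 had none, 50 had several, and 29 held a bare number, the form a spreadsheet gives to a symbol that looks like a date. Only probe sets with 1 symbol were named, and for the 1351 genes with more than 1 such probe set the one with the highest mean over all arrays was kept. This left 21104 genes, of which 18743 carry a current symbol and 1920 an older symbol in a mouse gene table of assembly GRCm38.p6. That table served only for names and for the order of genes along chromosomes. Symbols are printed as in the authors' table. All samples were mapped, and no column of sample values was left out.

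KO was compared with WT on the deposited log2 values in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior, no covariate), and p was adjusted over the 21104 genes by the Benjamini-Hochberg method with a threshold of 0.05. The prior carried 5.40 degrees of freedom. Signed differences are KO minus WT on the log2 scale, with the moderated standard error (SE). For single genes and for list scores an exact 2-sided permutation test of the difference of means over all 70 assignments of 4 against 4 pools was added. The smallest p this design can give is 0.0286, before any adjustment. Before the data were examined, 34 gene lists were fixed, and the 33 with at least 5 measured genes were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 33 lists. Camera with a correlation estimated per list, fry of limma and the exact test of the list score stand beside it. A list score is the mean over the list's genes of the deviation from each gene's mean over the 8 pools. In the lists, 9 genes were found under an older symbol. The remaining list, of Xist, Tsix and Y-linked genes, had too few measured members, and no Y-linked member was among the tested genes.

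The genes named in the text follow a rule fixed before the data were examined. They are Bmpr2 and Tjp1, then up to 12 genes per direction with an adjusted p under the threshold or, where fewer pass, the genes with the smallest p up to 6 per direction, and for each list up to 4 members with the largest absolute moderated t. Predicted genes, clones, microRNAs and other small RNAs, olfactory and vomeronasal receptors and major urinary proteins were left out of the second part, 4272 genes in all. A few genes that the rule would name are not reported here singly, although they stay in the tests over all genes and in their lists. Genes outside this rule were chosen after the data were examined. In the report these are Cd9, Id1, Smad6, Mecom, Hlf, Procr, Mpo, Elane and Xist. In the closing section Prtn3, Ctsg, Ms4a3, Fam169b and the genes singled out under the other observations were also chosen after their values were seen. The rule that reads a list's direction from the sign of its mean, where alternatives are compared, was set after results were seen.

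The procedure was tested on simulated data with the means and spreads of the 21104 genes, in 20 simulations with 200 changed genes each. Of genes changed 1.5-fold, 40.9% were recovered, of those changed 2-fold 82.7%, of those changed 3-fold 97.0% and of those changed 4-fold 99.3%. Among the calls, 4.82% were false. With fewer changed genes the adjusted threshold is harder to reach, and lower shares would be recovered. A list moved by 0.3 on the log2 scale was called in 20 of 20 simulations and no other list was called, with genes simulated as independent of each other, which real lists are not.

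The alternatives were filters on dim probe sets, median centring, a further quantile normalization, the annotated table in place of the table of values, another variance prior, array weights, the replicate number as a block, the mean of a gene's probe sets, Xist as a covariate for the sex of the pooled mice, other thresholds and leaving out each pool in turn. An analysis of all probe sets, named or not, was run as well. The sex covariate was planned as Y-linked genes minus Xist and used Xist alone, since no Y-linked list gene was measured. The adjustment of the authors' deposited p-values was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.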

Results

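RNA of HSCs, the marrow cells that can rebuild all blood lineages, was measured in 4 KO pools, which lack exons 4 and 5 of Bmpr2 in blood cells, and in 4 WT pools of littermates without Cre. Bmpr2 encodes a type II receptor for bone morphogenetic proteins (BMPs), and the comparison asks which transcripts differ in stem cells without it. All KO pools carried Vav-Cre and no WT pool did. An effect of the transgene therefore cannot be told apart from an effect of losing Bmpr2. Every mouse of the KO pools had both alleles floxed. The WT pools mixed genotypes, with 1, 0, 1 and 2 mice floxed on both alleles, 2, 3, 1 and 1 on a single allele, and 1 mouse of WT pool 3 on none. The arrays had nearly the same median level, between 5.58 and 5.69 on the log2 scale, but their spreads differed somewhat. The lower quartile lay between 4.19 and 4.31 in KO and between 4.23 and 4.37 in WT. The upper quartile lay between 7.17 and 7.26 in KO and between 7.10 and 7.23 in WT. A further quantile normalization, which makes the spreads alike, is among the alternatives. Across genes, pairs of arrays of the same group correlated with a median r of 0.986, and pairs of different groups with 0.985; genes are not independent replicates. WT pool 2 stood farthest from the others, with a median r of 0.982 to the other arrays against 0.985 to 0.987 for every other pool. Among transcripts of the gate's markers, Kit was at 10.20 ± 0.30 in KO and 10.35 ± 0.18 in WT, Cd9 at 8.91 ± 0.65 and 8.91 ± 0.62, and Slamf1, which encodes CD150, at 7.17 ± 0.35 and 6.90 ± 0.23 (log2, SD, n = 4).

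The deleted gene was lower in the KO pools without passing the test. Bmpr2 was at 6.87 ± 0.26 in KO and 7.65 ± 0.44 in WT (SD, n = 4), a difference of -0.79 (SE 0.21) or 1.72-fold lower. Its levels were 7.22, 6.64, 6.70 and 6.91 in KO pools 1 to 4 and 8.09, 7.63, 7.05 and 7.83 in WT pools 1 to 4, so that 3 of 4 KO pools lay below every WT pool and KO pool 1 lay above WT pool 3. The exact permutation p was 0.0571 and limma's adjusted p was 0.967. A probe set of this array type can cover exons outside the deleted part, and transcripts without exons 4 and 5 can still be detected there, so the level checks the labels only in part. The authors' deposited table gives the same gene a signed fold of -1.72.

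Tjp1, which encodes the scaffold protein ZO-1 of tight junctions, had the smallest p of all 21104 genes. Its level was 7.49 ± 0.46 in KO and 5.88 ± 0.27 in WT (SD, n = 4), a difference of 1.62 (SE 0.21), or 3.06-fold higher with a 95% interval from 2.21-fold to 4.24-fold. All 4 KO pools, between 7.13 and 8.12, lay above all 4 WT pools, between 5.51 and 6.13, which gives an exact permutation p of 0.0286, the smallest this design can give. Over all genes limma's adjusted p was 0.196 without a block, so Tjp1 did not pass. With the replicate number as a block, a grouping that the labels do not explain, Tjp1 had an adjusted p of 0.0193. Adjusted over the list alone, among the 36 measured genes of the tight junction list, it passed with an adjusted p of 0.000334. Tjp1 was picked for reporting by name from memory of the associated study, which was not used here and would have chosen it on these samples, so its place in that list is not independent evidence. The authors' deposited table gives Tjp1 a signed fold of 3.06.

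**Figure D1:**
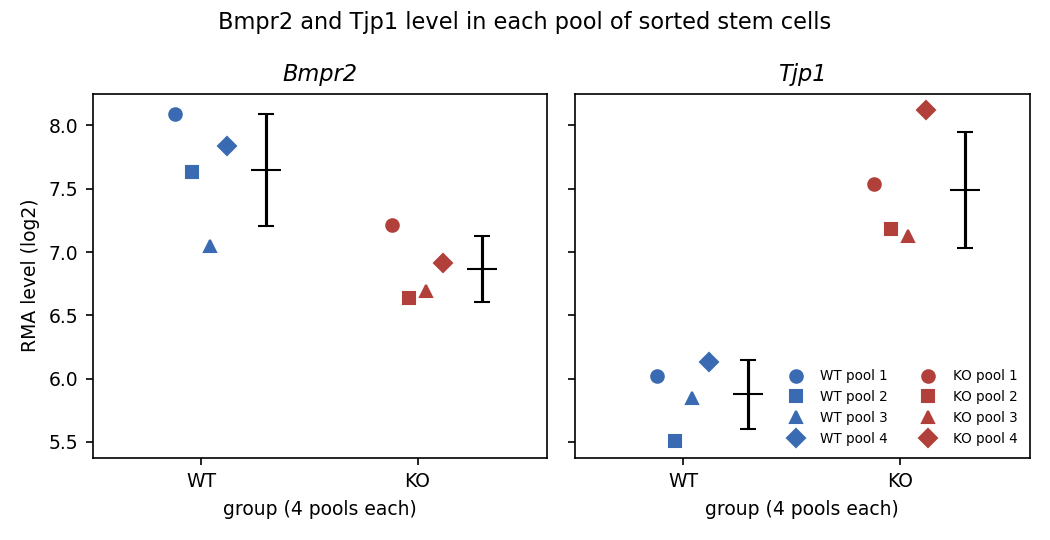
RMA level (log2, vertical axis) of Bmpr2 and Tjp1 in the 4 WT and 4 KO pools; each point is 1 pool, its shape gives the pool number, and the horizontal mark with its bar is the group mean ± SD. The KO pools lie between 6.64 and 7.22 for Bmpr2 and between 7.13 and 8.12 for Tjp1, against 7.05 to 8.09 and 5.51 to 6.13 in the WT pools.

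Over all genes, limma without a block called 0 higher and 0 lower in KO at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 960 genes, 486 higher and 474 lower, where 1055 would be expected with no change at all. The second smallest adjusted p after that of Tjp1 was 0.967. Adjusting the p-values of the authors' deposited table over the same genes also left 0 genes, with 913 genes under 0.05 before adjustment, of which 15 were at least 1.5-fold higher and 26 at least 1.5-fold lower. In the limma fit, 86 genes combined an unadjusted p under 0.05 with at least 1.5-fold, 32 higher and 54 lower. The groups of pools did not overlap for 545 genes, 2.58% of those tested, where chance gives 2.86%. In simulated data with 4 pools per group and 200 changed genes, a change of 1.5-fold was recovered for 40.9% of genes and a change of 2-fold for 82.7%. So many changed genes make the adjusted threshold easier to reach than here, where Tjp1 at 3.06-fold had a limma adjusted p of 0.196. With few changed genes, these rates overstate what the comparison could find.

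After Tjp1, the genes with the smallest p among those higher in KO were Tmod1, which encodes a protein that caps actin filaments, Fam105b, a deubiquitinase gene also known as Otulin, Gopc, which encodes a Golgi-associated scaffold protein, Parvb, which encodes an adaptor at integrin adhesions, and Parm1. Gopc was at 7.95 ± 0.18 in KO and 7.22 ± 0.27 in WT, a difference of 0.73 (SE 0.15). Parvb differed by 0.66 (SE 0.15), Parm1 by 0.62 (SE 0.14), Tmod1 by 0.55 (SE 0.11) and Fam105b by 0.54 (SE 0.11). Among those lower in KO, Slc15a2, a peptide transporter gene, was at 5.61 ± 0.38 in KO and 6.57 ± 0.27 in WT, a difference of -0.96 (SE 0.19) or 1.95-fold. Tbrg3 differed by -0.86 (SE 0.18), Rnf217 by -0.61 (SE 0.15), Rab6b, a GTPase gene of Golgi transport, by -0.54 (SE 0.10), Grrp1 by -0.47 (SE 0.11) and Rnf180 by -0.44 (SE 0.11). In each of these 11 genes all 4 KO pools lay beyond all 4 WT pools, and each had a limma adjusted p of 0.967.

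The 2 lists of the BMP pathway did not pass. Of 19 measured BMP target genes, 9 were higher and 10 lower in KO, with a mean difference of 0.06 (camera adjusted p = 0.598). The list's score was 0.124 in KO pool 4 and between -0.029 and 0.045 in the other KO pools. Id2 and Id3, which encode inhibitors of differentiation induced by BMP signalling, had the largest statistics, with Id2 at 5.11 ± 0.36 in KO and 4.73 ± 0.11 in WT and Id3 at 4.74 ± 0.47 and 4.15 ± 0.55 (SD, n = 4). The Id2 difference of 0.38 was 0.24 without KO pool 4, and the Id3 difference of 0.59 was 0.35 without WT pool 4. Id1 was at 5.78 ± 0.17 and 5.76 ± 0.18, and Smad6 at 5.49 ± 0.15 and 5.55 ± 0.15 (SD, n = 4). Of 36 other BMP and TGF-beta receptors, SMADs and modulators, 17 were higher and 19 lower (camera adjusted p = 0.736), among them Tgfb1 with a difference of 0.38 (SE 0.21) and Bmpr1a, a type I receptor, with 0.52 (SE 0.30), or 0.24 and 0.27 without KO pool 4. In both lists the median lay below 0 and the mean above it. No member of either list passed adjusted over the list alone or over all genes.

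Tjp1 was the only listed gene to pass when p was adjusted over its list alone, and over all genes no listed gene passed without a block. The tight junction list as a whole did not pass. Of its 36 measured, 18 were higher and 18 lower (camera adjusted p = 0.598). Csda, now called Ybx3, differed by 0.35 (SE 0.13) and Jam3, a junctional adhesion molecule, by -0.37 (SE 0.11). Among 33 genes of niche adhesion and homing, 23 were higher and 10 lower (camera adjusted p = 0.0624), with Alcam at 6.81 in KO and 7.27 in WT and Itgb2 at 7.47 and 7.10. The Alcam difference of -0.46 was -0.29 without KO pool 3, and that of Itgb2, 0.36, was 0.23 without WT pool 2. That list passed camera with the preset correlation without KO pool 2 (mean 0.14, adjusted p 0.0042) and without WT pool 1 (0.11, 0.0208). With all pools it passed when the replicate number was a block (0.080, 0.0409).

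Genes of the cell cycle were mostly higher in KO. Of 37 measured G2 and M phase genes 36 were higher, and the list's score was 0.134 ± 0.222 in KO and -0.134 ± 0.334 in WT (log2, SD, n = 4). The shift passed camera with the preset correlation (adjusted p = 3.41e-10) and was lost at an adjusted p = 0.836 with an estimated correlation. Of 34 S phase genes 30 were higher, with scores of 0.103 ± 0.237 and -0.103 ± 0.230. That list had a camera adjusted p of 4.48e-07 with the preset and likewise an adjusted p = 0.836 with an estimated correlation, which was 0.582. Ube2c, which marks mitotic proteins for destruction, differed by 0.49 (SE 0.12), the proliferation marker Mki67 by 0.47 (SE 0.16), the replication checkpoint gene Clspn by 0.41 (SE 0.11) and E2f8, a transcription factor of the cycle, by 0.48 (SE 0.16). Only 1 KO pool lay above all WT pools for G2 and M phase and 2 for S phase, and the exact permutation p was 0.257 for each list. No member passed adjusted over the list alone or over all genes. The G2 and M mean difference of 0.27 was 0.17 without KO pool 3 and 0.16 without WT pool 2. The S phase mean difference of 0.21 was 0.11 without KO pool 3 and 0.12 without WT pool 2. The granulocyte and monocyte list and the multipotent progenitor list, which also holds Mki67 and Top2a, with means of 0.19 and 0.18, shifted in the same direction.

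Lists of lineage and growth genes shifted upward with the preset correlation as well. Of 22 megakaryocyte and platelet genes 21 were higher, with a mean difference of 0.21 (camera adjusted p = 0.000111, adjusted p = 0.836 with an estimated correlation). They include Gp1ba, which encodes a platelet receptor for von Willebrand factor, with a difference of 0.60 (SE 0.18) and Gfi1b, a transcription factor of that lineage, with 0.47 (SE 0.15). Of 33 granulocyte and monocyte genes 24 were higher, with a mean of 0.19 (camera adjusted p = 0.0180, adjusted p = 0.836 with an estimated correlation), Cebpd differing by 0.47 (SE 0.18) and Ltf by 0.69 (SE 0.32), or 0.35 without KO pool 2. Of 19 multipotent progenitor genes 14 were higher, with a mean of 0.18 (camera adjusted p = 0.0109, adjusted p = 0.836 with an estimated correlation). Cd53, a tetraspanin gene of leukocytes, was at 5.61 in KO and 4.83 in WT, and the transcription factor gene Myc at 11.02 and 10.61. Of 37 MYC target genes 31 were higher, with a mean of 0.11 (camera adjusted p = 0.00109, adjusted p = 0.836 with an estimated correlation), Srm differing by 0.25 (SE 0.14), or 0.16 without KO pool 4 and 0.38 without KO pool 2. Of 50 oxidative phosphorylation genes 35 were higher, with a mean of 0.08 (camera adjusted p = 0.0110, adjusted p = 0.842 with an estimated correlation), Atp5o differing by 0.30 (SE 0.16), or 0.16 without WT pool 2, and Ndufa6 by -0.39 (SE 0.18). Leaving out KO pool 3 ended all 5 of these calls, with adjusted p of 0.0533 for the megakaryocyte list (mean 0.12), 0.0533 for granulocyte, 0.108 for multipotent progenitor, 0.392 for MYC (mean 0.051) and 0.734 for oxidative phosphorylation (mean 0.018). Leaving out WT pool 2 ended those of granulocyte (mean 0.098, adjusted p 0.163), multipotent progenitor (0.0702), MYC (mean 0.056, 0.163) and oxidative phosphorylation (mean 0.017, 0.612). The granulocyte call was also lost without KO pool 2 (mean 0.11, adjusted p 0.278) and WT pool 4 (0.111), and that of oxidative phosphorylation without WT pool 4 (mean 0.051, 0.227). The MYC mean was 0.17 without KO pool 2, and without WT pool 3 the granulocyte mean was 0.30 and that of oxidative phosphorylation 0.16. Among probe sets above the median level the calls of granulocyte (mean 0.31, adjusted p 0.352), multipotent progenitor (0.21, 0.0964), MYC (0.11, 0.0512) and oxidative phosphorylation (0.082, 0.213) were lost, although these means did not shrink. A further quantile normalization ended the calls of MYC (mean 0.055, adjusted p 0.196) and oxidative phosphorylation (mean 0.024, 0.459). Array weights ended those of granulocyte (mean 0.14) and oxidative phosphorylation (mean 0.061), with an adjusted p of 0.0527 each. Xist as a covariate ended that of granulocyte, with a mean of 0.22 (0.0515). No member of these 5 lists passed adjusted over the list alone or over all genes.

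A list of immediate early and sorting stress genes shifted the other way. Of 34 measured, 29 were lower in KO, with a mean of -0.11 (camera adjusted p = 0.0235, adjusted p = 0.836 with an estimated correlation). Dusp2, which encodes a phosphatase induced on activation, differed by -0.34 (SE 0.11) and Fosb by -0.35 (SE 0.18), or -0.19 without WT pool 4, while Myc, also a member, differed by 0.41 (SE 0.17). No member passed adjusted over the list alone or over all genes. WT pool 4 had a score of 0.422 for this list, against -0.132, 0.052 and -0.126 in the other WT pools. Without WT pool 4 the mean was 0.014, with an adjusted p of 0.881. The call was also lost without KO pool 2 (adjusted p 0.183) and WT pool 2 (0.0532), and the mean was -0.17 without WT pool 1 or WT pool 3. Array weights (adjusted p 0.0527) and Xist as a covariate (mean -0.071, 0.142) ended it as well.

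In all, 8 of 33 lists passed camera with the preset correlation of 0.01, 7 upward and 1 downward, 0 passed with an estimated correlation (limma's camera, 1 list at an unadjusted p under 0.05) and 0 passed fry (0 at an unadjusted p under 0.05). The number was 5 among probe sets above the median level, 5 with array weights, 3 without KO pool 3, 4 without WT pool 2 and 14 without WT pool 3. With the preset correlation, the S phase and G2 and M phase lists passed whichever pool was left out, although their estimated correlations were 0.582 and 0.65.

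**Figure D2:**
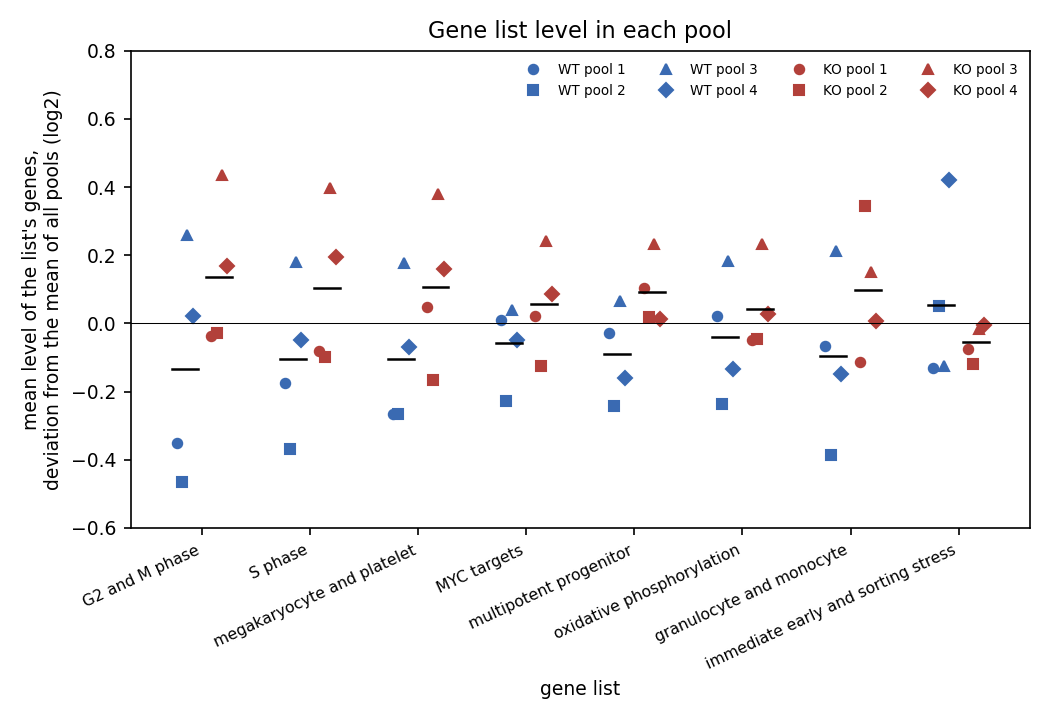
Score of the 8 lists that passed camera with the preset correlation (vertical axis, mean deviation of the list's genes from their mean over all pools, log2); each point is 1 pool, its shape gives the pool number, and the black line is the group mean. The groups overlap in every list: for G2 and M phase the KO pools lie between -0.037 and 0.436 and the WT pools between -0.466 and 0.259.

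The lists of stem cell identity and quiescence passed only under some alternatives. Of 49 HSC self-renewal and identity genes 16 were higher and 33 lower (camera adjusted p = 0.470). Mecom was at 7.76 ± 0.35 in KO and 7.87 ± 0.31 in WT, Hlf at 10.04 ± 0.31 and 10.21 ± 0.24 and Procr, which encodes EPCR, at 7.58 ± 0.43 and 7.71 ± 0.13 (log2, SD, n = 4), while Vldlr differed by 0.53 (SE 0.14) and Sult1a1 by -0.67 (SE 0.22). Of 27 quiescence genes 5 were higher and 22 lower, with a mean of -0.10 (camera adjusted p = 0.0624), and Btg1, an antiproliferative gene, differed by -0.42 (SE 0.19), or -0.24 without KO pool 2. WT pool 4 had a quiescence score of 0.311, against -0.004, -0.057 and -0.054 in the other WT pools, and without it the mean was -0.010 (adjusted p 0.852). With the preset correlation and all 8 pools, the quiescence list passed among probe sets above the median level (adjusted p 0.0142) or the 25th percentile (0.0460). It also passed with arrays centred on their medians (mean -0.062, 0.0489) and with the replicate number as a block (mean -0.097, 0.0409). A further quantile normalization let it pass (mean -0.14, 0.00601) and the HSC identity list as well (mean -0.081, 0.0458). With 1 pool left out, the quiescence list passed without KO pool 1 (-0.12, adjusted p 0.0207), WT pool 2 (-0.13, 0.00717) or WT pool 3 (-0.13, 0.0171), and the HSC identity list without KO pool 1 (-0.092, 0.0207) or WT pool 3 (-0.083, 0.0300). The 5 genes of the sort gate, with 3 higher and 2 lower, had a camera adjusted p of 0.879, and Cd48, which the gate selects against, was at 5.17 ± 0.72 in KO and 4.99 ± 0.65 in WT.

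Markers of other marrow cells were measured because the gate can let some through. Of 22 erythroid genes 15 were higher (camera adjusted p = 0.0899), among them Gata1 with a difference of 0.62 (SE 0.23). For 23 early lymphoid genes, 15 higher, the camera adjusted p was 0.470, and Flt3 was at 6.03 ± 0.28 in KO and 5.76 ± 0.23 in WT, a difference of 0.27, or 0.14 without KO pool 2. Of 18 macrophage genes 12 were higher (camera adjusted p = 0.470), with Hmox1 at 7.67 in KO and 7.09 in WT. With the preset correlation the erythroid list passed without KO pool 1 (mean 0.17, adjusted p 0.0497), KO pool 4 (0.20, 0.00222) or WT pool 3 (0.20, 0.00833), and the macrophage list without WT pool 3 (0.17, 0.0300). The 22 B cell genes (12 higher, adjusted p = 0.598), 21 T and NK cell genes (11 higher, 0.598), 15 mast cell and basophil genes (8 higher, 0.822), 22 endothelial genes (12 higher, 0.996) and 22 stromal and bone genes (10 higher, 0.344) did not pass camera either. Sparc, a matrix protein gene of the stromal list, differed by 0.71 (SE 0.28), Bst1 of the B cell list by -0.32 (SE 0.10) and Fcer1a of the mast cell list by 0.47 (SE 0.24), or 0.21 without KO pool 1. Abundant transcripts of granulocyte progenitors varied widely between pools, with Mpo at 6.70 ± 1.40 in KO and 6.03 ± 0.92 in WT and Elane at 5.77 ± 0.88 and 5.55 ± 0.52. No member of these lists passed adjusted over the list alone or over all genes.

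Of the remaining pathways, cholesterol synthesis and unfolded protein stress passed only under some alternatives. Camera's adjusted p was 0.0624 for 24 cholesterol synthesis genes (17 higher), 0.0925 for 28 genes of unfolded protein and amino acid stress (18 higher), 0.479 for 30 glycolysis and hypoxia genes (20 higher) and 0.598 each for 26 p53 targets (14 higher), 37 interferon response genes (21 higher), 22 NOTCH genes (14 higher), 29 WNT genes (15 higher) and 51 ribosomal protein genes (18 higher). It was 0.996 each for 32 genes of NF-kB and inflammation (15 higher) and 28 apoptosis genes (12 higher). Hsd17b7 of the cholesterol list differed by 0.51 (SE 0.20), Plk2 of the p53 list by -0.81 (SE 0.30), or -0.53 without KO pool 3, Ccng1 of the same list by 0.46 (SE 0.17), Ccnd1 of the WNT list by 0.39 (SE 0.14) and Dll4 of the NOTCH list by -0.31 (SE 0.13). With the preset correlation the cholesterol list passed with Xist as a covariate (mean 0.11, adjusted p 0.0347) and without KO pool 2 (mean 0.17, adjusted p 0.000441), WT pool 3 (0.10, 0.0267) or WT pool 4 (0.094, 0.0456). The unfolded protein list passed with the replicate number as a block (0.077, 0.0409) and without KO pool 2 (0.12, 0.00972), WT pool 3 (0.11, 0.0267) or WT pool 4 (0.10, 0.0336). Besides the BMP lists, the median, mean and test differed in sign for the stromal and bone, T and NK cell, WNT, B cell and mast cell lists, 7 lists in all. No member of these lists passed adjusted over the list alone or over all genes.

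**Figure D3:**
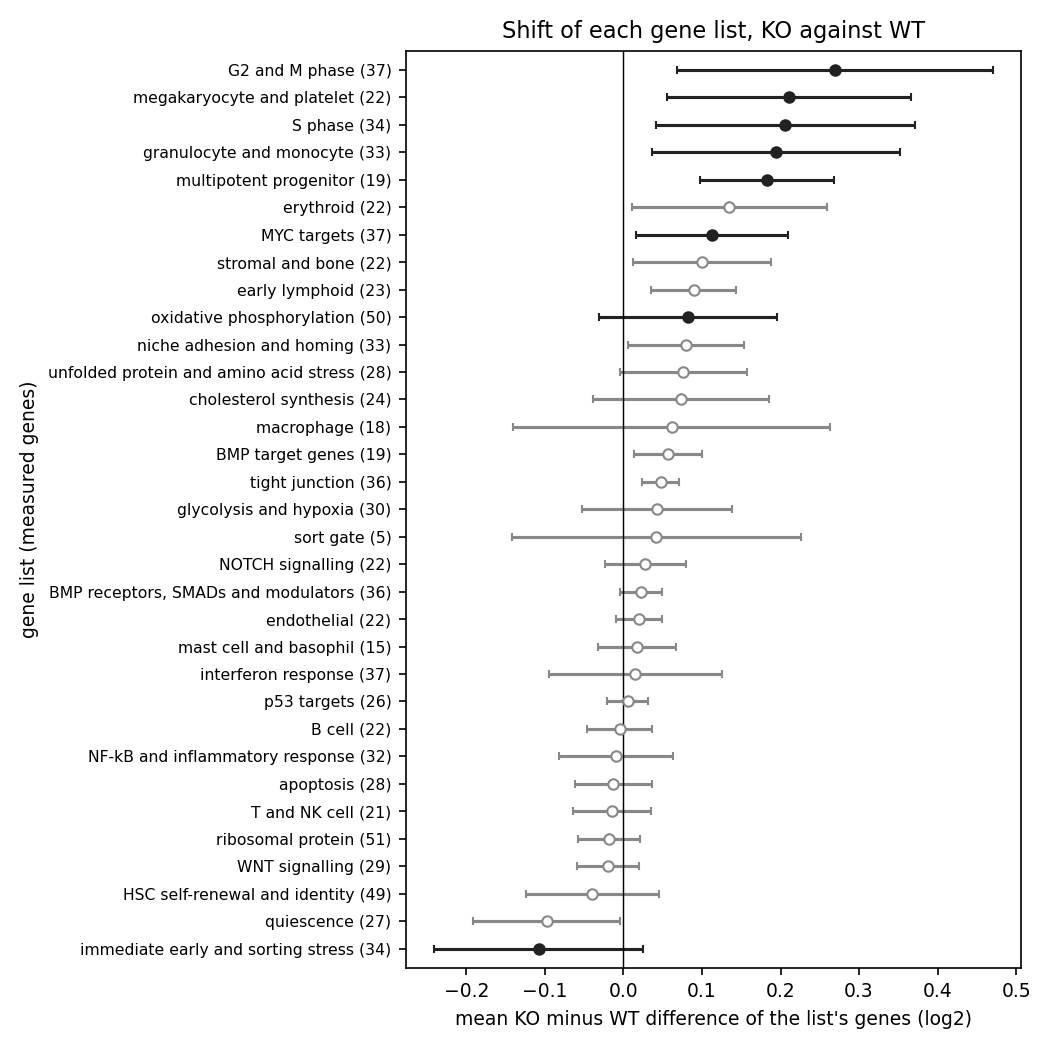
Mean KO minus WT difference (log2, horizontal axis) of each of the 33 gene lists, with the number of measured genes in brackets; bars are the standard error of the difference over 4 against 4 pools, and filled points mark the 8 lists that passed camera with the preset correlation. The mean differences run from -0.11 for immediate early and sorting stress genes to 0.27 for G2 and M phase genes.

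Xist, which is transcribed from the inactive X chromosome, split the pools across the groups, between 10.02 and 10.73 in KO pools 1 to 3 and at 10.57 and 9.96 in WT pools 1 and 2, against 4.38 in KO pool 4 and 4.52 and 4.21 in WT pools 3 and 4. With Xist as a covariate Tjp1 differed by 1.73 (SE 0.19, limma adjusted p = 0.0509), and over the alternatives tried its adjusted p ran from 0.0193 to 0.894.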

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

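The tests of Xist as a covariate on Tjp1, of granulocyte progenitor transcripts on the cell cycle lists and of the splits on the number of genes at an adjusted p under 0.05 were chosen only after results were seen.

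A pool far from the 3 others of its group was looked for in 330 groups of 4, and 13 held one, where chance gives about 16. Levels are on the log2 scale. Slc15a2 in KO pool 1 was at 6.18, with the others between 5.33 and 5.47. Bmpr1a in WT pool 1 was at 3.88 (others 2.80 to 2.93). Cd82 in WT pool 2 was at 7.68 (others 7.21 to 7.27), and Ndrg1 in the same pool at 7.76 (others 8.02 to 8.07). Btg1 in KO pool 2 was at 7.61 (others 8.34 to 8.37). In KO pool 4, Bst1 was at 3.93 (others 3.77 to 3.78), Cd68 at 6.92 (others 7.56 to 7.61), Rpl14 at 10.14 (others 9.88 to 9.92) and Sc5d at 7.88 (others 7.55 to 7.61). In WT pool 4, Fos was at 10.70 (others 9.90 to 9.97). For list scores, WT pool 4 had 0.311 for quiescence (others -0.057 to -0.0043), KO pool 1 had 0.279 for the interferon response (others -0.086 to -0.077) and WT pool 2 had -0.457 for the sort gate (others 0.112 to 0.137).

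Tjp1 was higher in all 4 KO pools, and it had the smallest p of all genes. A change shared by most of its chromosome region is argued against, since the median absolute moderated t of its 40 nearest measured genes lay at the 75.8th percentile of all windows of that size, although 4 of them had an unadjusted p under 0.05 (smallest 0.00893, for Fam169b, which differed by -0.55). The sex of the pooled mice is argued against as the whole cause, since with Xist as a covariate the difference was 1.73 (SE 0.187). Chance cannot be excluded: in 6 of the 35 splits of the 8 pools the largest absolute moderated t was as large as here, with 7.54 for Tjp1 and 9.03 in the highest other split. These splits take no account of the replicate numbers. With the number as a block, limma's adjusted p for Tjp1 was 0.0193, although the sources used here name no pairing by number. Loss of Bmpr2, or the Vav-Cre transgene that only the KO pools carry, may raise Tjp1 in stem cells. These 8 pools leave both hypotheses open and cannot tell them apart.

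The cell cycle lists were higher in KO, with a mean difference of 0.27 for G2 and M phase. With Xist as a covariate that difference was 0.353 (SE 0.175), which argues against sex as the cause. A single pool cannot be told apart from a shared shift, since without WT pool 2 the difference was 0.158 with an SE of 0.209. The bound set before the data were examined, below which the shift would rest on a single pool, was 0.134. The difference stayed above it, but by less than its SE. That the bound be passed by the SE was required, here and for Xist, only after results were seen. This SE takes no account of the replicate numbers. More granulocyte and monocyte progenitors in the KO pools could not be excluded either. Mpo, Elane, Prtn3, Ctsg and Ms4a3 differed by a mean of 0.182 with an SE of 0.152 over the 5 genes. That SE does not measure the spread between pools, which was wide, with an Mpo SD of 1.40 in KO and 0.92 in WT. KO pool 3 had the highest level of Mpo (8.18) and of Elane (6.94) among all pools. The other genes of the set did not follow: KO pool 3 had the lowest level of Prtn3, while Ctsg was highest in KO pool 2 and Ms4a3 in WT pool 3. The gate on Sca-1 and CD150 is meant to remove such cells, and the genes went both ways (0.67 for Mpo, 0.28 for Ctsg, 0.22 for Elane, -0.02 for Ms4a3 and -0.23 for Prtn3). In 19 of the 35 splits at least as many lists passed as the 8 found here, with 16 in the highest other split, so chance cannot be excluded. The splits take no account of the replicate numbers, and the one with 16 lists set pools 1 and 3 of both groups against the rest. A factor shared by number, if there is one, could raise the counts of such splits. The split of KO pools 1 and 2 with WT pools 1 and 2 against the rest gave the G2 and M list a smaller unadjusted p. With camera and the preset correlation it was 7.35e-22, against 1.03e-11 for KO against WT. A cell cycle effect of the deletion, or of Vav-Cre, stays an open hypothesis.

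For the number of genes at an unadjusted p under 0.05, chance cannot be excluded: there were 960, 16 of the 35 splits gave at least as many, and the highest other split gave 2059. At an adjusted p under 0.05 limma called 0 genes, a number that all 35 splits reach by construction, so the splits decide nothing there (highest other 1).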

How the results depend on the processing

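The adjustment of the authors' deposited p-values was chosen only after results were seen, and the other alternatives were planned. The number of genes at an adjusted p under 0.05 was 0 in 20 of 22 alternatives (limma, 960 at an unadjusted p under 0.05). It was 86 at an unadjusted p under 0.05 with at least 1.5-fold, a looser threshold by construction. With the replicate number as a block it was 2, Tjp1 (1.62, SE 0.13) and 7120432I05Rik (-1.31), each at an adjusted p of 0.0193; the cause was not tested. For the pairing, each gene's mean within KO or WT was subtracted and the deviations were correlated across genes. The deviations of KO and WT pools of the same number correlated at 0.287, 0.213, 0.305 and 0.0623, and those of different numbers at 0.0259 at most. The same-number values are not all above 0.1 and the sources used here name no pairing, so the numbers are not read as pairs. Yet in these deviations all 8 pools correlated best with their own number. The fit without a block and the splits do not allow for a factor shared by number. Over 18 alternatives the Tjp1 difference ran from 1.41 to 1.74 (adjusted p 0.0193 to 0.894) and that of Bmpr2 from -0.99 to -0.64 (adjusted p 0.544 to 1). Of the other genes that the naming rule chose, none passed under any alternative. RMA values near the background limit dim genes, and no background level is given in the files used here.

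The number of lists past the threshold was 8, and 5 among probe sets above the median level, where fewer genes are tested, 5 with array weights, 11 with the replicate number as a block, 0 with an estimated correlation (limma's camera, 1 list at an unadjusted p under 0.05), 0 with fry (0 at an unadjusted p under 0.05), and 3 to 14 with 1 pool left out. In the 8 lists the estimated correlation ran from 0.0526 for multipotent progenitor to 0.65 for G2 and M phase. All lay above the preset 0.01, which raises camera's p. Above the median level the means of MYC targets and oxidative phosphorylation stayed at 0.113 and 0.082, while camera's adjusted p rose to 0.0512 and 0.213. Those 2 calls were therefore lost without a change in the lists' own differences. Camera compares a list with the other genes tested, which were fewer and brighter there. After a further quantile normalization the 2 means were 0.055 and 0.024. The cause of the other differences was not tested. Over all lists and alternatives, 542 results kept their side and direction, 26 gained the call, 41 lost it and 48 turned. There were 7 lists that passed only under an alternative: quiescence in 8, unfolded protein stress and cholesterol synthesis in 4 each, HSC identity, niche adhesion and erythroid in 3 each and macrophage in 1.

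The mean turned for 15 lists, and 2 named genes turned, none past the threshold where it turned (lowest adjusted p 0.141). Apart from median centring, the cause was not tested. Above the median level the values were 0.079 for B cell, 0.15 for T and NK cell, -0.0095 for endothelial, 0.029 for NF-kB, 0.036 for WNT and 0.00068 for apoptosis. Above the 25th percentile they were 0.044 for B cell and 0.046 for T and NK cell. With arrays centred on their medians they were 0.030 for B cell, 0.021 for T and NK cell, 0.026 for NF-kB, 0.017 for ribosomal protein, 0.015 for WNT and 0.022 for apoptosis. Centring adds the same amount to the difference of every gene, so B cell moved from -0.0048 to 0.030 and Tjp1 from 1.615 to 1.65. Camera compares a list with the other genes, and its direction stayed down for each list that turned there. After a further quantile normalization they were 0.003 for B cell, 0.0093 for T and NK cell and -0.0092 for the interferon response. With the mean of a gene's probe sets B cell was at 0.0047. With Xist as a covariate T and NK cell was at 0.014, the interferon response at -0.010 and NF-kB at 0.0064.

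With 1 pool left out, the ranges of those that turned were -0.26 to 0.046 for Ly6a, -0.14 to 0.44 for Cd48, -0.092 to 0.012 for HSC identity, -0.026 to 0.041 for mast cell, -0.025 to 0.026 for B cell, -0.037 to 0.018 for T and NK cell and -0.10 to 0.17 for macrophage. They were -0.075 to 0.071 for the interferon response, -0.053 to 0.029 for NF-kB, -0.17 to 0.014 for immediate early and sorting stress, -0.0060 to 0.026 for p53, -0.027 to 0.10 for glycolysis and -0.046 to 0.0070 for ribosomal protein. They were -0.040 to 0.0096 for WNT, -0.058 to 0.0094 for apoptosis and -0.10 to 0.12 for the sort gate.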

Other observations

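Both tests on the genes between Dlk1 and Dio3 were chosen only after results were seen, and all genes named in this part were chosen after their values were seen.

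Of genes that differed at least 2-fold, 2 were higher in KO, Tjp1 and Xist, and 9 were lower, among them the small RNA genes Mir99a, Mir32, Mir15a, Scarna8 and Snord57. Mir99a, a microRNA gene, was at 4.86 ± 1.42 in KO and 6.24 ± 0.79 in WT (log2, SD, n = 4), a difference of -1.38 (SE 0.60). 2810055G20Rik, an older symbol of its host gene in the gene table of assembly GRCm38.p6, differed by -0.81 (SE 0.44) and Mirlet7c-1 by -0.10 (SE 0.34). Mir32 differed by -1.37 (SE 0.46) and Mir15a by -1.20 (SE 0.30). 7120432I05Rik, which has no match in that table, was at 4.73 ± 0.40 in KO and 6.04 ± 0.51 in WT. With Tjp1 it was 1 of the 2 genes in this group whose pools did not overlap, where chance gives 2.86% of all genes. That rate is no measure for this group, which was chosen for large differences, where pools that do not overlap are likelier. None of these genes passed in limma without a block, with an adjusted p of 0.967 for Mir99a, Mir32, Mir15a, 2810055G20Rik and 7120432I05Rik. With the replicate number as a block, Tjp1 and 7120432I05Rik each had an adjusted p of 0.0193.

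Of the 5188 probe sets with no symbol, 255 had an unadjusted p under 0.05. That is less than the share of 0.05 expected with no change at all. The largest statistics among them belonged to 10375121 and 10375123, which differed by -1.86 (SE 0.30) and -1.81 (SE 0.29), with all 4 KO pools below all 4 WT pools in each (limma adjusted p = 0.814, exact permutation p 0.0286). They correlated with each other at 0.9999 over the 8 pools, so they count as 1 observation. Their gene is not given in the files used here.

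Meg3, an imprinted noncoding RNA gene, was at 6.26 ± 0.55 in KO and 7.22 ± 0.38 in WT (limma adjusted p = 0.967), with KO pool 2 at 7.08 above WT pool 1 at 7.07 and WT pool 3 at 6.74. Of 46 measured genes between Dlk1 and Dio3 31 were lower, with a mean of -0.085 (exact permutation p 0.143). Of the 46, 2 had an unadjusted p under 0.05 in limma, both lower. The region's median and mean were no lower than those of small RNA genes elsewhere. Lower activity particular to this imprinted region is therefore not shown, but it is not excluded either. Some of its microRNA probe sets lay near the lowest deposited value of 1.47, such as Mir376c at 1.81 in KO and 1.87 in WT. Probe sets that dim could hardly show a decrease. Others lay far higher, such as Mir667 at 8.27 in KO and 8.37 in WT. The median of 336 small RNA genes elsewhere was -0.0639 and their mean -0.10, with 219 lower, against a median of -0.054 for the region, and medians this close to 0 over genes that go both ways do not decide whether small RNA probe sets had a lower signal as a class. Meg3 is a long noncoding RNA gene and not of that class. Without WT pool 2 the mean of the region was -0.0384, against -0.085 over all pools, so much of the region's mean rests on that pool.

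The 40 measured genes nearest to Bmpr2 in gene order had a median absolute moderated t at the 62.4th percentile of all windows of that size, and 0 of them had an unadjusted p under 0.05 in limma. The smallest unadjusted p among them was 0.0554, for Clk1, which differed by -0.33.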
